A study of Arabidopsis thaliana with 24 samples.

How the data were processed

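Polysome-bound mRNA of whole Arabidopsis seedlings was measured by strand-specific paired-end sequencing in 24 libraries, 3 replicates for each of 8 groups (wild type or exa1-1, in MS, NaCl, 23 °C or 39 °C). Per the submitters' processing notes, HISAT2 2.0.4, HTSeq 0.6.1p1 and the genome build TAIR10 were used; trimming, strand and overlap settings and the annotation release are not stated, so genes of near-identical families are uncertain. The authors deposited a table of counts for 32833 genes, of which 5150 have no count in any library. A second table, deposited by the authors, holds FPKM for the other 27683 genes. On the values, each FPKM equals the count times a constant of the gene over the column total, with a largest relative difference of 1.26e-09 over 19702 genes checked. Library totals ran from 17861136 to 20629439, and 0 of 276 pairs of libraries were identical.

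Groups were read from the sample titles, and each experiment was analysed with its own control. The groups, the comparisons, the tests, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The replicate numbers were tested as pairs: correlations of residuals between libraries with the same number exceeded 0.1 in 0 of 30 cases, so the samples were not paired. A batch field in the labels has the same entry for all samples and could not be used.

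Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries scaled by TMM, and groups compared by quasi-likelihood tests with robust dispersions, in fits of 12 libraries per experiment and of all 24 for the comparison of the controls. A gene is called at a Benjamini-Hochberg adjusted p under 0.05, without a minimum fold; adjusted p-values in the text come from edgeR for genes and from limma's camera for lists. There were 12 comparisons: salt and heat within each genotype, genotype within each of 4 conditions, 2 interactions, and 23 °C against MS within each genotype. Values are log2 fold changes with SE, and levels are mean CPM with SD. The common biological coefficient of variation was 0.0455 in the salt fit and 0.0539 in the heat fit. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.

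Gene lists were 24 sets of locus identifiers (383 genes, all in the table) and 4 sets by rule on names or genome, 28 in all. Each was tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation; both adjusted p-values are given, the latter after the word estimated. Members are counted as called over all genes and, separately, as called when adjusted over the list alone; "by either count" means that the 2 gave the same numbers. After the data were examined 2 lists were added, of genes whose annotation note names the cytosolic or the chloroplast ribosome, because the rule on names took only part of the family.

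Genes to name were fixed by rule: per comparison EXA1, the 5 called genes with the largest change each way among those with a symbol, a mean of at least 5 CPM and replicates that do not overlap between groups (for interactions without the last condition), and up to 4 members per list, with at most 30 in the text. Chance alone parts 3 against 3 replicates without overlap in 10% of splits. The rule named 1425 entries over the 12 comparisons, of which 1333 were called and 143 lost their call without some library; the text gives a part of them, picked after the values were seen. Where a group had no count the fold is a bound against a floor of 3 counts over the group, and with 1 to 3 counts a ratio with its 95% counting interval.

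Tests were tried only on simulated data: 200 genes changed, groups as for wild-type salt. Of 50 genes per size, 58%, 88%, 100% and 100% were recovered at 1.25, 1.5, 2 and 4-fold, with 11 of 184 calls false. For the interaction these were 20%, 76%, 96% and 100%, and 10 of 156. Camera called 0 of 50 random lists, but correlated lists and shifts as broad as in heat were not tried.

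Alternatives tried were RLE size factors, library totals alone, DESeq2 1.42.0, limma-trend on log2 FPKM with a pseudocount of 1 or 0.1 (genes with a mean FPKM of at least 0.5), no filter or a stricter filter (1 CPM in 6 libraries), a replicate block, all 24 libraries or only those compared, organellar genes left out, a 2-fold minimum, an estimated correlation, the region within 500 kb of EXA1 left out, and leaving out each library in turn. Chosen after the data were examined was a trend of each library on coding length and GC content, taken off before the test of the 26 lists whose genes have a coding length. Ribosome loading per transcript was not estimated, since no total RNA was analysed here.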

Results

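Polysome-bound mRNA was sequenced from whole seedlings of Arabidopsis thaliana, aged 9 days, of the wild type (Col-0) and of the exa1-1 mutant, which carries a lesion in a gene for a GYF-domain protein. Messages recovered with polysomes are those loaded with several ribosomes, so each value is an abundance in the polysome fraction. No total RNA was analysed here, and changes in transcript abundance and in ribosome loading therefore cannot be told apart. Seedlings were treated for 60 min in 2 experiments, each with its own unstressed control. In the salt experiment seedlings on MS medium without or with 200 mM NaCl were compared, and in the heat experiment seedlings at 23 °C or 39 °C. Each of the 8 groups had 3 independent biological replicates, 24 libraries in all, and total gene counts ran from 17861136 to 20629439 per library.

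EXA1 (AT5G42950; TAIR10.1 chromosome 5, 17224270 to 17231384, plus strand, 10 exons) was examined first in every group, as a check of the genotype labels. In the wild type its mean level, in CPM (counts scaled to library size), was 52.7 ± 0.830 in MS, 76.4 ± 1.41 in NaCl, 103 ± 2.37 at 23 °C and 96.0 ± 3.26 at 39 °C (SD, n = 3 each). The mutant libraries held 7.74 ± 0.551, 5.56 ± 0.546, 7.31 ± 0.891 and 8.16 ± 1.17 CPM in the same order. EXA1 in exa1-1 was thus at 14.8%, 7.28%, 7.11% and 8.50% of its wild-type level, with log2 fold changes of −2.76 (SE 0.069), −3.78 (SE 0.074), −3.81 (SE 0.078) and −3.56 (SE 0.09), and the lowest wild-type library lay above the highest mutant one in all 4 conditions. Salt raised EXA1 in the wild type (log2 fold change 0.53, SE 0.053, adjusted p = 1.53e-11) and lowered it in exa1-1 (−0.50, SE 0.097, adjusted p = 2.03e-05), and this difference between genotypes passed its own test (−1.02, SE 0.111, adjusted p = 2.62e-09). Heat left EXA1 without a call in either genotype (−0.08, adjusted p = 0.209, in the wild type and 0.18, adjusted p = 0.175, in exa1-1).

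**Figure D1:**
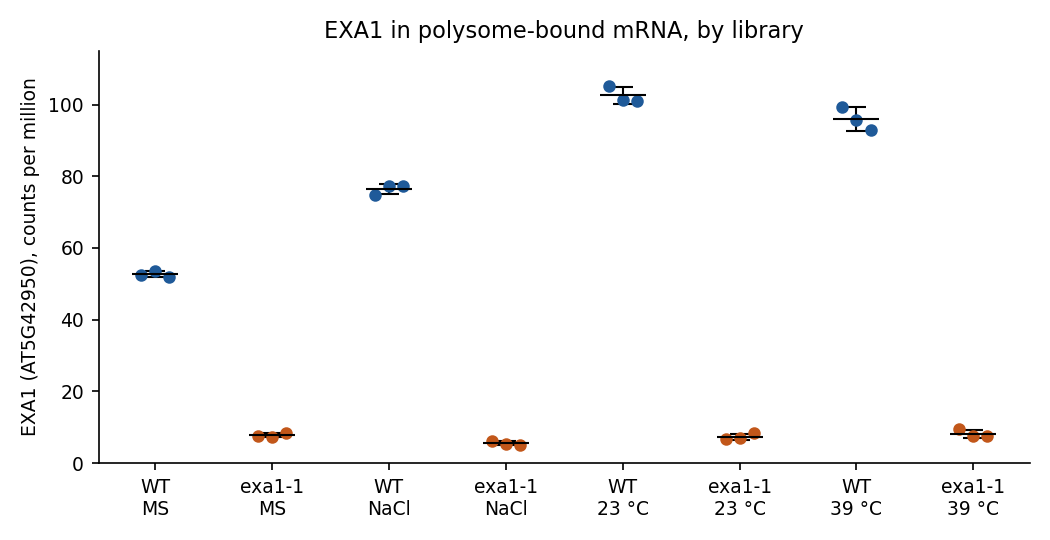
Level of EXA1 (CPM, vertical axis) in each of the 24 libraries, by group (horizontal axis); points are libraries and bars show the mean and SD of 3 replicates. The wild-type means lie between 52.7 and 103 CPM and the mutant means between 5.56 and 8.16 CPM.

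**Figure D2:**
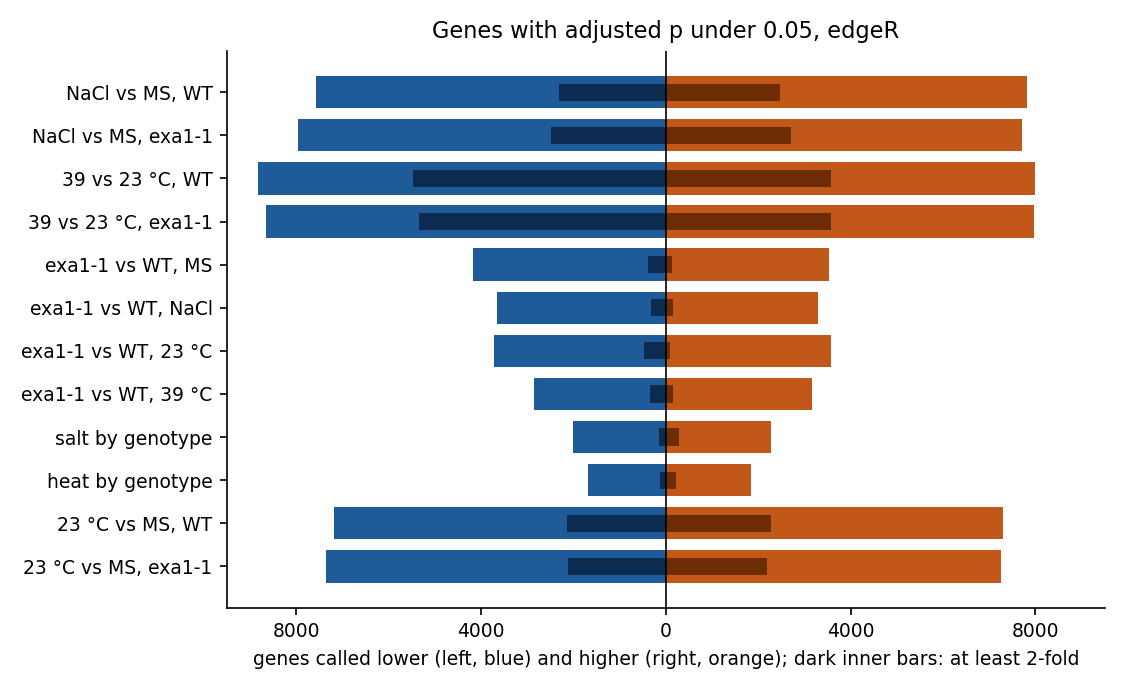
Number of genes called higher or lower (horizontal axis, genes at an adjusted p under 0.05 by edgeR's quasi-likelihood test with TMM scaling) in each of the 12 comparisons (vertical axis). The stress and control comparisons call between 14486 and 16839 genes, the genotype comparisons between 6030 and 7717, and the interactions 4291 and 3533; with library totals as the only scaling 3007 genes rise and 15476 fall with heat in the wild type.

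Among the genes that rose with salt in the wild type were many of osmotic stress and abscisic acid (ABA), the hormone of water deficit. LEA4-5, which encodes a protective late embryogenesis abundant protein, went from 1.11 ± 0.393 to 470 ± 10.4 CPM (log2 fold change 8.70, SE 0.082, n = 3 per group, adjusted p = 9.57e-46). GolS2, of the galactinol synthases that make raffinose-family osmolytes, rose from 0.0845 to 35.8 CPM (8.66, SE 0.201), TSPO from 0.148 to 60.4 CPM (8.58, SE 0.148) and the phosphatase gene HAI2 from 0.196 to 71.1 CPM (8.48, SE 0.158). The transcription factor gene BHLH92 had so few counts in MS that only a ratio with its counting interval is given, 687 (95% interval 235 to 3332). Among the falls were the receptor-like kinase gene CRK30, with a ratio of 422 between MS and NaCl (117 to 3492), and the ABA receptor gene PYL6 (−6.41, SE 0.138). The root hair genes RHS19 (−5.71, SE 0.201) and RHS13 (−4.86, SE 0.154) and the small heat shock gene HSP15.4 (−5.14, SE 0.105) fell as well.

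All 33 genes of the ABA and osmotic response list rose in the wild type, both over all genes and adjusted over the list alone (median log2 fold change 3.63, adjusted p = 1.44e-17, with an estimated correlation 0.000198). They included LTI65, also known as RD29B (7.24, SE 0.199), and the caleosin gene RD20 (6.44, SE 0.08). All 8 measured clade A protein phosphatase genes, negative regulators of ABA signalling, rose as well, 8 adjusted over the list alone (median 3.38, adjusted p = 2.97e-06, estimated 0.0114). Among them HAI3 was at 7.70 (SE 0.228). ABA receptor genes went the other way, with 7 of 9 lower and 2 higher by either count (median −1.68, adjusted p = 0.0058, but 0.0921 with an estimated correlation). PYL4 went from 223 to 14.4 CPM (−3.96, SE 0.068). The 11 genes of the DREB1 cold list, most of which are also on the ABA list, all rose, 11 adjusted over the list alone (median 3.63, adjusted p = 2.95e-07, estimated 0.00654). LTI78, or RD29A, reached 2980 CPM from 118 (4.66, SE 0.053). COR15A rose by 5.44 (SE 0.065) and DREB1A, nearly uncounted in MS, had a ratio of 76.7 (25.9 to 375). Of the jasmonate genes 17 of 18 rose and 0 fell, 17 adjusted over the list alone (median 1.59, adjusted p = 3.55e-08, estimated 0.00278). Examples are LOX2 (3.91, SE 0.067) and JAZ7 (3.26, SE 0.125).

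Genes of the endoplasmic reticulum (ER) protein folding list fell in the wild type, 11 of 14 with 2 higher, the same adjusted over the list alone (median −1.24, adjusted p = 9.5e-05, estimated 0.0312). CNX1, the lectin chaperone calnexin, fell by 1.73 (SE 0.041) while the transcription factor gene BZIP60 rose (1.42, SE 0.047). Cell division genes fell, 14 of 15 by either count (median −0.90, adjusted p = 3.57e-05, estimated 0.0246), with PCNA1 at −1.98 (SE 0.095) and AUR1 at −1.58 (SE 0.144). Root markers fell too, 13 of 16 with 2 higher by either count (median −1.08, adjusted p = 0.000585, estimated 0.0183), EXPA18 among them (−2.63, SE 0.122). All 12 autophagy genes rose, 12 adjusted over the list alone (median 0.74, adjusted p = 5.59e-05, estimated 0.0114), with ATG8H (2.04, SE 0.07). Heat shock regulators rose in 9 of 14 and fell in 2, or 3 adjusted over the list alone (median 0.74, adjusted p = 0.0112, estimated 0.0489). Pattern-triggered immunity genes rose in 15 of 19 and fell in 3 by either count (median 0.87, adjusted p = 0.0058, estimated 0.0312). Mitochondrion-encoded transcripts, a measure of organellar RNA in the libraries, fell in 12 of 14 by either count (median −1.34, adjusted p = 0.00449, estimated 0.0312). Their share went from 0.0281% ± 0.0009 to 0.0142% ± 0.0008 of counts, mostly mitochondrial ribosomal RNA (0.0257% and 0.0134%).

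The other calls of lists in the wild type under salt were lost with an estimated correlation. Photosynthesis genes rose in 35 of 41 and fell in 1 by either count (median 0.68, adjusted p = 6.15e-08, estimated 0.233), with PSBO2 of photosystem II at 1.40 (SE 0.109). Small heat shock genes rose in 10 of 14 and fell in 2 (median 1.21, adjusted p = 0.0123, estimated 0.0921), with HSP26.5 at 4.76 (SE 0.231). Ethylene genes rose in 8 of 10 (adjusted p = 0.043, estimated 0.133, and 0.0514 with a replicate block), clock genes in 12 of 17 (0.0178, estimated 0.0588). Antioxidant enzyme genes rose in 7 of 11 (0.043, estimated 0.299, 0.0515 without WT NaCl replicate 2 and 0.0522 with a replicate block). Chloroplast-encoded genes fell in 25 of 44 (median −0.73, adjusted p = 0.00108, estimated 0.156). The list of ribosomal proteins of the cytosol by name fell in 12 of 17, or 13 adjusted over the list alone (median −0.41, adjusted p = 0.0058, estimated 0.142). Sodium transport genes did not pass as a list (adjusted p = 0.322), although the vacuolar exchanger gene NHX1 rose (1.40, SE 0.045) and the sodium carrier gene HKT1 fell (−1.09, SE 0.232). Salicylate defence genes (0.724), NLR immune receptors (0.796), translation factors with partners of EXA1 (0.936), auxin and growth genes (0.936), and aquaporins (0.409) did not pass either. The same holds for shoot markers (0.936), HSP70, HSP90 and HSP100 chaperones (0.381) and nuclear genes for organellar ribosomal proteins (0.212).

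By edgeR's quasi-likelihood test 15407 of 21453 genes were called with salt in the wild type, 7823 up and 7584 down. Scaled by library totals alone the split was 6174 up and 9518 down, with the median of all genes at −0.15 on the log2 scale. Small positive medians of 5 uncalled lists turned negative there.

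Many of the same genes rose with salt in exa1-1. LEA7, nearly uncounted in the mutant in MS, reached 99.6 ± 2.80 CPM, a ratio of 3686 (95% counting interval 1020 to 30440). MYB121, with no count in MS, was at least 266-fold higher in NaCl (floor of 3 counts over the group). LEA4-5 rose from 0.545 ± 0.0966 to 553 ± 10.9 CPM (log2 fold change 9.95, SE 0.09, n = 3 per group, adjusted p = 1.4e-46). HAI2 rose by 9.16 (SE 0.173), and BHLH92 had a ratio of 780 (216 to 6448). CRK30 (−7.67, SE 0.24), PYL6 (−7.20, SE 0.136), the cell wall gene FLA9 (−5.89, SE 0.154), HSP15.4 (−5.69, SE 0.113) and RHS13 (−5.07, SE 0.139) fell.

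The ABA and osmotic list rose in 32 of 33 genes in exa1-1 by either count (median 4.07, adjusted p = 7.84e-18, estimated 0.000188), with LTI65 at 8.61 (SE 0.191). All 8 phosphatase genes rose, 8 adjusted over the list alone (median 3.34, adjusted p = 4.01e-06, estimated 0.0116), with HAI3 at 8.89 (SE 0.222). The 11 cold list genes all rose, 11 adjusted over the list alone (median 4.54, adjusted p = 2.11e-07, estimated 0.00576). COR15A rose by 5.71 (SE 0.06), and DREB1A had a ratio of 75.8 (20.6 to 632). Jasmonate genes rose in 17 of 18 by either count (median 2.00, adjusted p = 1.79e-08, estimated 0.00245), for instance LOX3 (3.66, SE 0.136). Ethylene genes rose in 9 of 10 with 1 lower by either count (median 1.3, adjusted p = 0.000977, estimated 0.025), for instance ACS2 (3.97, SE 0.126). Pattern-triggered immunity genes rose in 14 of 19 with 4 lower by either count (median 1.00, adjusted p = 0.00346, estimated 0.025), for instance CYP71A13 (3.58, SE 0.427). Small heat shock genes rose in 12 of 14 with 1 lower by either count (median 2.01, adjusted p = 0.000324, estimated 0.025), HSP26.5 by 5.20 (SE 0.224). All 12 autophagy genes rose, 12 adjusted over the list alone (median 0.83, adjusted p = 4.95e-05, estimated 0.0116), ATG8H by 2.38 (SE 0.074). All 15 cell division genes fell, 15 adjusted over the list alone (median −1.06, adjusted p = 9.51e-06, estimated 0.0171), with PCNA1 at −2.03 (SE 0.097) and MCM2 at −1.61 (SE 0.104). So did 13 of 16 root markers with 2 higher (median −1.51, adjusted p = 0.000324, estimated 0.0141), with EXPA18 at −3.64 (SE 0.12). ER folding genes fell in 11 of 14 with 3 higher by either count (median −0.69, adjusted p = 0.00346, but 0.0737 with an estimated correlation). CNX1 fell by 1.17 (SE 0.04), while the stress-induced BIP3 had a ratio of 39.98 (13.3 to 197) over MS.

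Salt in exa1-1 changed 15672 of 21453 genes by the same test, 7701 up and 7971 down, or 5850 up and 10357 down with library totals alone, where the median of all genes was −0.20. Of the 28 fixed lists 21 passed with the preset correlation and 12 with an estimated one.

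Whether the salt response differed between genotypes was tested as an interaction, where a positive value means a larger rise or smaller fall in exa1-1. The detoxification gene GSTU3 rose from 0.161 to 11.2 CPM in exa1-1 and had an interaction of 4.31 (SE 0.336, adjusted p = 5.16e-13). SAG13 had one of 2.90 (SE 0.197) and ELI3-2 one of 2.79 (SE 0.12). LTP4 and LEA7 were nearly uncounted in exa1-1 in MS, so that their fitted interactions of 3.76 (SE 0.609) and 3.18 (SE 0.747) depend on the prior count. The ratio of NaCl to MS in exa1-1 was 439 for LTP4 (95% counting interval 150 to 2134). Lower values in exa1-1 were found for the defensin genes PDF1.2c (−2.41, SE 0.338) and PDF1.2 (−1.40, SE 0.228), which share sequence and therefore perhaps reads. They were also found for the root growth factor gene RGF9 (−1.45, SE 0.216), for BZIP34 (−1.31, SE 0.26, but −0.5 and not called with log2 FPKM + 1) and for SVL2 (−1.29, SE 0.095).

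ER folding genes had a positive interaction in 11 of 14 and a negative one in 0, or 12 and 0 adjusted over the list alone (median 0.50, adjusted p = 2.7e-09, estimated 0.0138). BIP2, nearly identical to BIP1, stood at 0.68 (SE 0.079) and CRT1a at 0.58 (SE 0.061). In 18 of 33 ABA and osmotic genes the rise was larger in exa1-1 and in 2 smaller, or 21 and 2 adjusted over the list alone (median 0.47, adjusted p = 1.26e-08, estimated 0.00326). NCED3 stood at 1.64 (SE 0.214). The cold list was positive in 7 of 11 and negative in 0, or 9 and 0 adjusted over the list alone (median 0.82, adjusted p = 4e-05, estimated 0.0176). KIN1, close in sequence to KIN2, was at 1.18 (SE 0.152) and ERD10 at 0.91 (SE 0.066). Ethylene genes were positive in 6 of 10 and negative in 0, or 7 and 0 adjusted over the list alone (median 0.44, adjusted p = 2.38e-05, estimated 0.0176). The synthesis gene ACS8 was at 1.93 (SE 0.207) and ERF5 at 0.78 (SE 0.12). Unlike ER folding, the ABA, cold and ethylene lists had no genotype call in NaCl (adjusted p = 0.126, 0.0727 and 0.229). In MS they were lower in exa1-1. Root markers were negative in 5 of 16 and positive in 0, or 6 and 0 adjusted over the list alone (median −0.31, adjusted p = 0.00192, estimated 0.0353). EXPA18 was at −1.0 (SE 0.198).

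The remaining interaction calls were lost with an estimated correlation. Photosynthesis genes were negative in 26 of 41 and positive in 0, or 29 and 0 adjusted over the list alone (median −0.29, adjusted p = 3.79e-12, estimated 0.214), with PSBX at −0.73 (SE 0.063). Aquaporins were positive in 12 of 18 and negative in 1, or 13 and 2 (median 0.41, adjusted p = 5.71e-07, estimated 0.0838), with PIP1A at 0.96 (SE 0.056). Small heat shock genes were positive in 8 of 14 (median 0.97, adjusted p = 0.00129, estimated 0.0622), with HSP17.6II at 1.80 (SE 0.278). The larger chaperones were positive in 7 of 13 (median 0.33, adjusted p = 0.00192, estimated 0.151), with HSP101 at 0.46 (SE 0.092), as were auxin genes in 7 of 16 (median 0.09, adjusted p = 0.0113, estimated 0.0669), with IAA19 at 1.91 (SE 0.146). The call of the cell division list (1 of 15 negative, median −0.21, adjusted p = 0.0452, estimated 0.22) was lost without any 1 of 7 libraries (0.0915 without WT MS replicate 1), and with library totals alone (0.0514) or a replicate block (0.0546). MCM2 itself was called (−0.91, SE 0.148).

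The salt interaction called 4291 of 21453 genes, 2284 positive and 2007 negative, or 2008 and 2322 with library totals alone. Relative to the wild-type response 1599 of them were larger in exa1-1, 1412 smaller and 560 of opposite sign, and 720 were not called in the wild type. Of the 560, 233 were called in both genotypes.

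Heat in the wild type raised genes of heat shock proteins, molecular chaperones that bind unfolding proteins. ATHSP22.0, a small heat shock protein of the ER with no count at 23 °C, reached 9967 ± 285 CPM at 39 °C, at least 201600-fold higher (floor of 3 counts over the group, n = 3 per group). HSP23.6-MITO went from 0.133 ± 0.0764 to 9401 ± 45.0 CPM (log2 fold change 16.04, SE 0.079, adjusted p = 2.33e-73). Its level at 23 °C rests on few counts, so this SE is likely too small. HSP17.6C, HSP17.6A-CI and HSP17.6II rose by 15.41 (SE 0.067), 14.53 (SE 0.071) and 14.28 (SE 0.172). The ubiquitin ligase gene ATL8 fell, with a ratio of 504 between 23 °C and 39 °C (95% counting interval 90.3 to 19930). So did the trans-acting siRNA precursor TAS3 (−6.36, SE 0.288), UCC2 (−5.95, SE 0.13), bZIP3 (−5.76, SE 0.319) and OXS3 (−5.72, SE 0.147).

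Of the 15 small heat shock genes 14 rose and 1 fell by either count (median log2 fold change 13.89, adjusted p = 9.02e-09, estimated 0.00255). Close members of this family share sequence, and how their reads were divided is uncertain. All 13 larger chaperone genes rose, 13 adjusted over the list alone (median 7.77, adjusted p = 3.44e-10, estimated 0.00255). Hsp70b rose from 9.33 to 10360 CPM (10.13, SE 0.053), HSP101 to 10180 CPM (10.02, SE 0.058) and HSP90.1 to 12010 CPM (9.75, SE 0.049). All 14 heat shock regulators rose, 14 adjusted over the list alone (median 4.12, adjusted p = 2.22e-07, estimated 0.00326). HSFA2 was at 12.93 (SE 0.106), MBF1C at 8.50 (SE 0.075) and DREB2A at 6.30 (SE 0.06). ER folding genes rose in 13 of 14 with 1 lower by either count (median 2.01, adjusted p = 5.38e-06, estimated 0.0178). BIP2 rose by 4.63 (SE 0.046) and CNX1 by 3.72 (SE 0.042), opposite to their fall under salt. The ABA and osmotic list rose in 21 of 32 with 7 lower by either count (median 1.40, adjusted p = 0.000913, estimated 0.0173; 17 up and 13 down with library totals alone, median 0.493), with the galactinol synthase gene GolS1 from 13.3 to 3172 CPM (7.92, SE 0.051). All 8 measured cold list genes rose, 8 adjusted over the list alone (median 5.13, adjusted p = 2.42e-05, estimated 0.0178), KIN1 by 6.80 (SE 0.149) and LTI78 by 5.57 (SE 0.061).

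Mitochondrion-encoded transcripts rose in 28 of 30 and fell in 0, by either count (median 3.27, adjusted p = 3.22e-06, estimated 0.00326), with a median of 1.793 over the 5 genes with at least 20 counts in each library. They made up 0.117% ± 0.0013 of counts at 39 °C against 0.0382% ± 0.0012 at 23 °C. Most of that share was mitochondrial ribosomal RNA, 0.107% ± 0.0012 against 0.0358% ± 0.0011, and the other mitochondrial genes went from 0.0024% to 0.0102%. Nuclear ribosomal RNA went from 0.0138% ± 0.0005 down to 0.0062% ± 0.0004. The gene atp1, with 1 count at 23 °C, had a ratio of 54.0 (95% counting interval 8.96 to 2206). Photosynthesis genes rose in 40 of 41 by either count (median 1.97, adjusted p = 4.95e-16, but 0.0562 with an estimated correlation). Examples are LHCB2.1, of the light-harvesting family whose copies share reads (5.00, SE 0.058), and PSAO (3.05, SE 0.042). Pattern-triggered immunity genes fell in 12 of 18 with 2 higher by either count (median −1.27, adjusted p = 0.0145, estimated 0.0841), among them the flagellin receptor gene FLS2 (−3.66, SE 0.17) and PHI-1 (−4.35, SE 0.121). Auxin genes fell in 14 of 16 with 2 higher by either count (median −2.62, adjusted p = 0.0145, estimated 0.0794), with SHY2, or IAA3, at −4.85 (SE 0.193). Among antioxidant genes, not called as a list (7 of 11 up, adjusted p = 0.0903, but 0.0202 with library totals alone, where 5 rose and 5 fell with a median of 0.014), the peroxidase gene APX2 rose by 12.03 (SE 0.12).

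Heat shifted the libraries as a whole. With library totals alone the median of all genes in the wild type fell by 1.00 on the log2 scale, against −0.10 with TMM. Then 3007 genes rose and 15476 fell in place of 7999 and 8840. Under that scaling the medians of the lists above kept their signs, while those of 2 other called lists turned. Translation factors rose in 15 of 21 with TMM (median 0.29, adjusted p = 0.0113, estimated 0.193; eIFiso4G2 3.12, SE 0.052) but had a median of −0.62 and adjusted p = 0.703 with totals. Nuclear genes for organellar ribosomal proteins rose in 7 of 8 (median 0.85, adjusted p = 0.0172, estimated 0.366) but had a median of −0.06 and adjusted p = 0.0589. The pattern-triggered immunity and auxin lists lost their calls with totals (adjusted p = 0.0619 and 0.254). EXA1 itself lay at −0.99 in the wild type and −0.78 in exa1-1 with totals alone, both called.

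Heat shock genes also rose with heat in exa1-1. HSP17.6C rose from 0.767 ± 0.162 to 17450 ± 344 CPM (log2 fold change 14.49, SE 0.063, n = 3 per group, adjusted p = 2.36e-75), and ATHSP22.0 from 0.580 to 10720 CPM (14.19, SE 0.08). Others were HSP17.4 at 13.60 (SE 0.061), the chloroplast small heat shock gene HSP21 at 13.43 (SE 0.076) and HSP26.5 at 13.28 (SE 0.108). OXS3 (−6.49, SE 0.184), TAS3 (−5.89, SE 0.264), UCC2 (−5.88, SE 0.138), NAC1, a root development regulator (−5.86, SE 0.174), and SHY2 (−5.57, SE 0.24) fell.

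Of the small heat shock genes 14 of 15 rose with 1 lower by either count (median 13.22, adjusted p = 2.43e-08, estimated 0.003). The 13 larger chaperones all rose, 13 adjusted over the list alone (median 8.02, adjusted p = 2.93e-10, estimated 0.00287), with HSP101 at 15330 ± 338 CPM and HSP90.1 at 16010 ± 358 CPM. The 14 heat shock regulators all rose, 14 adjusted over the list alone (median 4.23, adjusted p = 1.69e-07, estimated 0.003), HSFA2 by 12.80 (SE 0.104). ER folding genes rose in 12 of 14 with 2 lower by either count (median 2.26, adjusted p = 0.000126, estimated 0.0402), BIP2 by 4.39 (SE 0.045). BIP3, with 2 counts at 23 °C, had a ratio of 19.5 (4.69 to 172). The ABA and osmotic list rose in 20 of 32 with 6 lower by either count (median 2.48, adjusted p = 0.000692, estimated 0.0155; 18 up and 13 down with totals alone, median 1.527), GolS1 by 8.46 (SE 0.052). The 8 cold list genes all rose, 8 adjusted over the list alone (median 4.55, adjusted p = 4.59e-05, estimated 0.0209), LTI78 by 4.91 (SE 0.059). Mitochondrion-encoded transcripts rose in 28 of 30, 28 adjusted over the list alone (median 3.66, adjusted p = 2.31e-06, estimated 0.003), to 0.131% ± 0.0024 of counts from 0.0314% ± 0.0021, of which ribosomal RNA made 0.12% and 0.0294%. Calls lost with an estimated correlation were those of photosynthesis (40 of 41 up, adjusted p = 4.31e-16, estimated 0.0557; PSAO 2.86, SE 0.042), phosphatases of ABA signalling (7 of 8 up, 0.0292, estimated 0.147; HAI2 3.56, SE 0.403) and antioxidant enzymes (8 of 11 up, 0.0179, estimated 0.154; APX2 11.97, SE 0.116). With totals alone the phosphatases were 3 up and 3 down (median 0.276) and the antioxidant genes 6 up and 5 down (median 0.449). Lost as well were those of pattern-triggered immunity (13 of 18 down, 0.0179, estimated 0.105; FLS2 −3.47, SE 0.174) and auxin (12 of 16 down, 0.0465, estimated 0.147), both lost also with library totals alone (0.202 and 0.47). The calls of translation factors (17 of 21 up, 0.00731, estimated 0.153, with totals 0.592) and organellar ribosomal proteins (7 of 8 up, 0.0271, estimated 0.363, with totals 0.0756) were lost both ways, and the translation factor median of 0.23 became −0.73 with totals. The auxin call was also lost without exa1 23 °C replicate 2 (0.0563) or 3 or any 1 exa1 39 °C replicate.

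Heat changed 16839 of 20923 genes in the wild type and 16622 in exa1-1 (7961 up and 8661 down). With library totals alone the mutant split was 2888 up and 15679 down and the median of all genes fell by 1.05.

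The heat response was compared between genotypes in the same way. Larger rises in exa1-1 were called for ELI3-2 (interaction 2.65, SE 0.375, adjusted p = 8.26e-07), the stress-associated zinc finger gene PMZ (2.17, SE 0.313) and the glutathione transferase gene GSTU25 (1.99, SE 0.186). SAP10, with no count in exa1-1 at 23 °C, was at least 357-fold higher at 39 °C, and its fitted interaction of 4.18 (SE 1.26, adjusted p = 0.0152) was not called without WT 23 °C replicate 3 (3.75) or with log2 FPKM + 1 (0.248). GDPD6, with 1 count in exa1-1 at 23 °C, had a fitted interaction of 2.93 (SE 1.07, adjusted p = 0.049), which fell to 1.70 without WT 23 °C replicate 1 and was no longer called there. It was not called either without WT 39 °C replicate 1 or 2, exa1 23 °C replicate 1 or 3 or any 1 of the exa1 39 °C replicates. The call of GDPD6 was also lost with RLE size factors, library totals alone (2.99), a replicate block, DESeq2 (3.36), all 24 libraries in 1 fit (3.02) and log2 FPKM with either pseudocount (0.087 and 0.832). Smaller rises or larger falls in exa1-1 were called for ATHSP22.0 (−6.06, SE 0.77), HSP23.6-MITO (−2.81, SE 0.308), the glucosyltransferase gene UGT73C1 (−2.54, SE 0.44), SQP1 (−2.47, SE 0.432) and XPL1, a phosphoethanolamine methyltransferase (−2.31, SE 0.165). In wild type and mutant at 39 °C ATHSP22.0 stood at 9967 and 10720 CPM and HSP23.6-MITO at 9401 and 10940 CPM. At 23 °C ATHSP22.0 was at 0 and 0.580 CPM and HSP23.6-MITO at 0.133 and 1.14 CPM. The fitted value of ATHSP22.0 therefore depends on the prior count.

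Of the 28 lists 5 passed with the preset correlation and 0 with an estimated one. Small heat shock genes were negative in 7 of 15 and positive in 1 by either count (median −0.62, adjusted p = 0.00431, estimated 0.0583), as HSP17.6A-CI (−1.56, SE 0.225). The list was higher in exa1-1 at 23 °C, near 1 CPM, and not called at 39 °C (0.763). Larger chaperones were positive in 7 of 13 and negative in 0, or 10 and 0 adjusted over the list alone (median 0.25, adjusted p = 0.00431, estimated 0.0583, and 0.0751 with a trend on coding length and GC content taken off). Hop3 was at 0.61 (SE 0.08) and HSP90.1 at 0.37 (SE 0.067). ER folding genes were negative in 8 of 14 and positive in 0, or 9 and 0 adjusted over the list alone (median −0.26, adjusted p = 0.000408, estimated 0.0583), the reverse of their interaction under salt. PDIL1-1 was at −0.64 (SE 0.063) and CRT1b at −0.61 (SE 0.063). Cell division genes were negative in 2 of 15, 1 adjusted over the list alone (median −0.28, adjusted p = 0.034, estimated 0.106, and 0.0508, 0.0538 and 0.0647 without replicate 2 of WT 23 °C, WT 39 °C or exa1 39 °C). SYP111 was at −0.84 (SE 0.143). Chloroplast-encoded genes were positive in 4 of 47, 4 adjusted over the list alone (median 0.32, adjusted p = 0.0278, estimated 0.0583, and 0.0539 without exa1 39 °C replicate 2), with psaA at 1.39 (SE 0.338).

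In all, 3533 of 20923 genes had a called heat interaction, 1838 positive and 1695 negative, or 1387 and 2255 with library totals alone. The response was larger in exa1-1 for 1371 of them, smaller for 1375 and of opposite sign for 364, and 423 were not called in the wild type. Of the 364, 139 were called in both genotypes.

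The mutant was compared with the wild type in each condition in turn. In MS, lists of growth and of defence genes stood lower in exa1-1, as given below. No list of plant defensin genes was tested. MRD1 rose from 0.309 ± 0.124 to 9.83 ± 1.22 CPM (log2 fold change 5.00, SE 0.231, n = 3 per group, adjusted p = 1.28e-20). The defensin genes PDF1.2 and PDF1.3, targets of jasmonate and ethylene signalling that share reads with their near-identical copies, rose by 3.90 (SE 0.165) and 3.57 (SE 0.141). TZP, a light-signalling gene on the same chromosome as EXA1 (1.48, SE 0.066), and CORI3, a jasmonate-responsive gene (1.27, SE 0.066), rose too. Besides EXA1, genes that fell were ELI3-2 (−2.62, SE 0.106), the expansin gene EXPA8 (−2.23, SE 0.162), the auxin-response gene IAA19 (−1.93, SE 0.113) and the desaturase gene ADS1 (−1.88, SE 0.133).

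All 16 measured auxin and growth genes fell in MS, 16 adjusted over the list alone (median −1.58, adjusted p = 2.75e-13, estimated 0.00119). Among them was IAA29 (−2.82, SE 0.208). Ethylene genes fell in 9 of 10 by either count (median −0.66, adjusted p = 2.71e-07, estimated 0.00549), with ACS8 at −1.79 (SE 0.167) and ERF2 at −1.32 (SE 0.077). Jasmonate genes fell in 13 of 18 with 1 higher, or 15 and 2 adjusted over the list alone (median −0.40, adjusted p = 5.58e-06, estimated 0.00549). JAZ10 was at −1.15 (SE 0.077) and VSP2 at −0.95 (SE 0.076), although PDF1.2 and CORI3 went up. Salicylate defence genes fell in 12 of 22 with 2 higher by either count (median −0.49, adjusted p = 0.000286, estimated 0.0163). BGL2, the pathogenesis-related glucanase PR2, was at −2.38 (SE 0.185), and PBS3, an enzyme of salicylate synthesis, at −1.68 (SE 0.181). Pattern-triggered immunity genes fell in 10 of 19 with 1 higher by either count (median −0.29, adjusted p = 0.00178, estimated 0.0227), for example the camalexin gene CYP71A13 (−2.72, SE 0.474). The ABA and osmotic list fell in 18 of 33 with 2 higher, or 19 and 2 adjusted over the list alone (median −0.57, adjusted p = 1.58e-05, estimated 0.00549), with NCED3 at −1.43 (SE 0.207). Small heat shock genes fell in 9 of 14 by either count (median −0.74, adjusted p = 1.58e-05, estimated 0.017), with HSP17.6II at −1.79 (SE 0.207). Aquaporins, water channels of the plasma membrane and vacuole, fell in 15 of 18 with 1 higher by either count (median −0.50, adjusted p = 6.77e-09, estimated 0.0446), with RD28 at −0.75 (SE 0.064).

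Lost with an estimated correlation were the calls of photosynthesis (36 of 41 down, 38 adjusted over the list alone, median −0.56, adjusted p = 7.31e-22, estimated 0.0798; LHCB3 −1.19, SE 0.05) and ER folding (8 of 14 down, adjusted p = 0.00283, estimated 0.0876). Lost as well were the cold list (6 of 11 down, 0.0247, estimated 0.096) and nuclear genes for organellar ribosomal proteins (5 of 8 down, 0.0179, estimated 0.325). BIP3 of the ER list, with 3 counts in exa1-1, was 27.0 times lower than in the wild type (95% counting interval 8.91 to 134). Root markers were not called (5 of 16 up and 1 down, median 0.096, adjusted p = 0.0504) and passed without WT MS replicate 2 or exa1 MS replicate 1 or 3 (0.0239). Their share of counts was 0.0221% in the wild type and 0.0288% in exa1-1. That of shoot markers, not called (0.237), was 0.639% and 0.542% and that of photosynthesis genes 2.903% and 2.204%. Larger chaperones (0.0578), heat shock regulators (0.0553), autophagy genes (0.0553) and ribosomal proteins by name (0.0957) also passed without 1 library. In MS, 7717 of 21453 genes differed, 3535 higher and 4182 lower in exa1-1, and library totals alone gave 5717 higher and 2951 lower. Library exa1 MS replicate 3 stood apart from its own group, with a chi-square per degree of freedom of 5.06 and 6.57 against replicates 1 and 2, where these 2 gave 2.44.

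In NaCl the defensin gene PDF1.3 again rose in exa1-1, from 7.29 ± 1.08 to 49.7 ± 4.14 CPM (log2 fold change 2.77, SE 0.095, n = 3 per group, adjusted p = 4.71e-24). PDF1.2 rose by 2.51 (SE 0.103) and PDF1.2c by 2.36 (SE 0.119). COR15A, which protects chloroplast membranes on dehydration, rose from 332 to 801 CPM (1.27, SE 0.046) and the nuclease gene ENDO2 by 1.24 (SE 0.102). NdhM of the chloroplast NDH complex (−2.29, SE 0.15), the defence genes ACD6 (−1.88, SE 0.146) and BGL2 (−1.86, SE 0.139) and the light-harvesting gene LHB1B2, whose copies share reads (−1.79, SE 0.12), fell.

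Auxin and growth genes fell in 13 of 16 in NaCl by either count (median −0.69, adjusted p = 4.24e-06, estimated 0.0188), the only 1 of the 28 lists past the threshold with both correlations. SAUR19, with 3 counts in exa1-1 and close copies nearby, was 18.23 times lower (95% counting interval 5.91 to 91.2). All 41 photosynthesis genes fell, 41 adjusted over the list alone (median −0.80, adjusted p = 2.23e-34, but 0.0663 with an estimated correlation). Shoot markers, not called (4 of 10 down and 1 up, adjusted p = 0.116), made up 0.942% ± 0.0203 of counts in the wild type and 0.542% ± 0.0085 in exa1-1. Whether the tissues contributed in other proportions was not tested. LHCB3 was at −1.46 (SE 0.049) and RBCS1B, of a family with shared reads, at −1.61 (SE 0.361, not called in a fit of the 6 libraries alone). ER folding genes rose in 10 of 14 with 2 lower, or 11 and 2 adjusted over the list alone (median 0.28, adjusted p = 0.000177, estimated 0.0663), BIP2 by 0.49 (SE 0.057) and CRT1a by 0.48 (SE 0.045). Jasmonate genes fell in 10 of 18 with 1 higher, or 10 and 2 adjusted over the list alone (median −0.23, adjusted p = 0.00492, estimated 0.0663), with JAZ7 at −0.78 (SE 0.096) and LOX2 at −0.67 (SE 0.051). The call of nuclear genes for organellar ribosomal proteins (4 of 8 down, adjusted p = 0.0422, estimated 0.372) was lost without replicate 1 or 3 of either group. Salicylate defence genes, not called (10 of 22 down, adjusted p = 0.0612), passed with library totals alone (0.0329) and without any 1 of 3 libraries. FMO1, of systemic acquired resistance, was at −1.45 (SE 0.278) and the shoot marker CA1 at −1.02 (SE 0.04). Under salt 6950 of 21453 genes differed, 3281 higher and 3669 lower, or 4608 and 2878 with library totals alone.

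At 23 °C the defensin gene PDF1.2b stood higher in exa1-1, from 0.915 ± 0.12 to 15.1 ± 1.55 CPM (log2 fold change 4.03, SE 0.176, n = 3 per group, adjusted p = 1.4e-25). PDF1.3 rose by 3.65 (SE 0.164), PDF1.2c by 3.45 (SE 0.121) PDF1.2 by 3.23 (SE 0.107) and the seed storage gene CRU3 by 1.75 (SE 0.181). CYP71A12 (−2.54, SE 0.177) and PAD3 (−1.98, SE 0.154), enzymes of indolic defence compounds, the germin-like gene GLP9 (−2.20, SE 0.123) and the cell wall gene XTH15 (−2.06, SE 0.048) were lower.

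Salicylate defence genes fell in 15 of 21 with 0 higher, or 15 and 1 adjusted over the list alone (median −0.94, adjusted p = 7.98e-07, estimated 0.0321), with FMO1 at −2.38 (SE 0.256) and PBS3 at −1.85 (SE 0.229). Pattern-triggered immunity genes fell in 10 of 18 with 2 higher, or 11 and 2 adjusted over the list alone (median −0.54, adjusted p = 0.00382, estimated 0.0478), with CYP71A13 at −3.48 (SE 0.401). Jasmonate genes fell in 8 of 17 with 1 higher by either count (median −0.34, adjusted p = 0.00207, estimated 0.0321), with LOX4 at −1.41 (SE 0.323). Ethylene genes fell in 7 of 10 by either count (median −0.43, adjusted p = 0.00283, estimated 0.0321), with ACS8 at −1.98 (SE 0.523). Of the ABA and osmotic list 18 of 32 fell with 3 higher, or 20 and 4 adjusted over the list alone (median −0.42, adjusted p = 0.00207, estimated 0.0321), with NAC019 at −1.84 (SE 0.36). Auxin and growth genes fell in 12 of 16, 13 adjusted over the list alone (median −1.0, adjusted p = 0.000163, estimated 0.0321), with IAA29 at −3.18 (SE 0.539). Aquaporins fell in 15 of 18 with 1 higher, or 16 and 1 (median −0.42, adjusted p = 9.17e-10, estimated 0.0321) and clock genes in 10 of 18 with 1 higher by either count (median −0.24, adjusted p = 0.00207, estimated 0.0321). Chloroplast-encoded genes fell in 10 of 47, or 9 adjusted over the list alone (median −0.26, adjusted p = 0.0129, estimated 0.0321).

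Upward, small heat shock genes rose in 6 of 15 with 1 lower by either count (median 0.67, adjusted p = 0.00283, estimated 0.0321), at levels near 1 CPM. HSP23.6-MITO rose by 3.02 (SE 0.302), and HSP17.6A-CI by 1.67 (SE 0.221), and ATHSP22.0, uncounted in the wild type, was at least 11.4-fold higher. ER folding genes rose in 10 of 14 with 2 lower by either count (median 0.32, adjusted p = 2.61e-05, estimated 0.0321), CRT1a by 0.80 (SE 0.046) and CRT1b by 0.65 (SE 0.045). In contrast BIP3, with 2 counts in exa1-1, was 12.6 times lower (95% counting interval 3.13 to 110). Calls lost with an estimated correlation were those of photosynthesis (32 of 41 down, adjusted p = 4.85e-13, estimated 0.0578; LHCB3 −0.84, SE 0.04), autophagy (6 of 12 down, 0.00207, estimated 0.0777; ATG8H −0.94, SE 0.099) and translation factors with partners of EXA1 (10 of 21 up, 0.00207, estimated 0.0855; EIF4G 0.55, SE 0.06). So were those of ribosomal proteins by name (10 of 17 up, 0.000527, estimated 0.12), cell division (6 of 15 up, 0.0186, estimated 0.0578; CDKB1_1 0.66, SE 0.177), ABA phosphatases (3 of 8 down, 0.0381, estimated 0.122) and shoot markers (5 of 10 down, 0.0186, estimated 0.12). The phosphatase call was lost without WT 23 °C replicate 2 or 3 or exa1 23 °C replicate 1 or 2 (0.102), and the shoot marker call without exa1 23 °C replicate 3 (0.0532). At 23 °C 7283 of 20923 genes differed, 3568 higher and 3715 lower. With a 2-fold minimum more genes were lower than higher in each condition, 393 and 127 in MS, 327 and 146 in NaCl, 472 and 94 at 23 °C and 351 and 160 at 39 °C. Libraries WT 23 °C replicates 1 and 3 differed from each other more than any other replicate pair, with a chi-square per degree of freedom of 6.60.

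At 39 °C MRD1 (log2 fold change 5.78, SE 0.362, n = 3 per group, adjusted p = 5.67e-19, at 10.5 ± 1.05 CPM in exa1-1) was higher in exa1-1. So were the defensin genes PDF1.3 (3.58, SE 0.184), PDF1.2 (3.05, SE 0.102) and PDF1.2b (2.77, SE 0.164), together with the seed storage gene CRA1 (2.83, SE 0.192). XPL1 (−2.69, SE 0.142), CYP71A12 (−2.45, SE 0.201), SQP1 (−2.08, SE 0.201) and the cell wall gene XTH18 (−1.85, SE 0.185) were lower.

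Larger chaperones rose in 12 of 13 in exa1-1 at 39 °C by either count (median 0.27, adjusted p = 1.67e-05, estimated 0.0275), the only 1 of the 28 lists past both tests there. HSP101 stood at 15330 ± 338 against 10180 ± 147 CPM (0.59, SE 0.036), Hsp70b at 14990 against 10360 CPM (0.53, SE 0.033) and CLPB4 at 633 against 419 CPM (0.59, SE 0.044). The small heat shock list was not called (9 of 15 up, adjusted p = 0.763), and HSP15.4 of this list fell by 1.13 (SE 0.135). Salicylate defence genes fell in 11 of 21, 13 adjusted over the list alone (median −0.93, adjusted p = 0.000104, estimated 0.053). BGL2 was at −3.29 (SE 0.313), FMO1 at −1.82 (SE 0.231) and PBS3 at −1.94 (SE 0.413). Pattern-triggered immunity genes fell in 7 of 18, 8 adjusted over the list alone (median −0.49, adjusted p = 0.00624, estimated 0.0966), with YLS9, or NHL10, at −2.84 (SE 0.457) and CYP71A13 at −2.56 (SE 0.416). Aquaporins fell in 14 of 18 by either count (median −0.38, adjusted p = 6.97e-10, estimated 0.0611). Clock genes fell in 10 of 18, or 11 with 1 higher adjusted over the list alone (median −0.22, adjusted p = 0.00203, estimated 0.053), with PRR5 at −1.34 (SE 0.093), and photosynthesis genes in 32 of 41 with 2 higher by either count (median −0.34, adjusted p = 1.18e-13, estimated 0.107), with LHCB3 at −0.87 (SE 0.038). Translation factors with partners of EXA1 rose in 11 of 21 with 3 lower, or 12 and 3 adjusted over the list alone (median 0.19, adjusted p = 0.00256, estimated 0.137, and 0.142 with a trend on coding length and GC content taken off). EIF4G, the cap-binding scaffold, rose by 0.62 (SE 0.068).

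Several calls at 39 °C rested on single libraries as well as on the preset correlation. They were those of the ABA and osmotic list (11 of 32 down, adjusted p = 0.0484, estimated 0.118; lost with totals alone, 0.0709, with a replicate block, 0.0558, and without WT 39 °C replicate 2 or 3, 0.103, or exa1 39 °C replicate 1 or 3) and ABA receptors (6 of 9 down, 0.0216, estimated 0.164; without WT 39 °C replicate 3, 0.0685). The same applies to auxin genes (3 of 16 down, 0.0404, estimated 0.137; with totals alone, 0.0907, and without WT 39 °C replicate 2 or exa1 39 °C replicate 3) and autophagy genes (7 of 12 down, 0.0285, estimated 0.21; without WT 39 °C replicate 2, 0.0533). It applies also to ribosomal proteins by name (7 of 17 up, 0.0329, estimated 0.422; without WT 39 °C replicate 1 or 2 or exa1 39 °C replicate 2). IAA19 was at −1.21 (SE 0.226) and the ABA receptor gene PYL7 at −0.56 (SE 0.058). NAC019 (−1.77, SE 0.548, adjusted p = 0.0106) was not called without exa1 39 °C replicate 2 (−1.56) or with log2 FPKM + 1 (−0.471). At 39 °C 6030 of 20923 genes differed, 3170 higher and 2860 lower, or 2482 and 3565 with library totals alone.

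**Figure D3:**
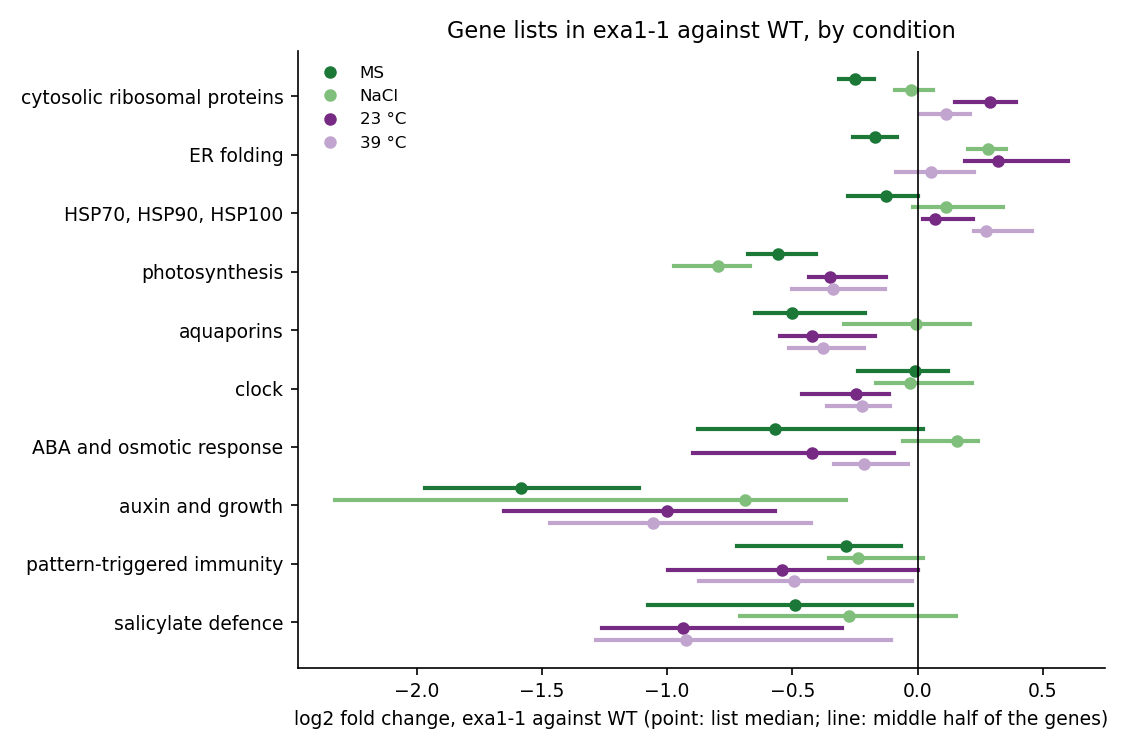
Median log2 fold change of exa1-1 against the wild type (horizontal axis; points, with bars from the lower to the upper quartile of the members) for 10 gene lists (vertical axis) in each of the 4 conditions. Auxin and growth genes lie below 0 in all 4, at −1.58, −0.69, −1.0 and −1.06 in MS, NaCl, 23 °C and 39 °C, and cytosolic ribosomal proteins, a list added after the data were examined, at −0.25, −0.03, 0.29 and 0.11, where the value in NaCl turns to 0.03 with library totals alone.

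Across the 4 conditions the genotype difference was shared by a set of genes. Among 20552 genes tested in all 4, 248 were called higher in exa1-1 in every one, where 14.5 would be expected from independent lists, and 509 lower, where 17.7 would be expected. Without genes within 500 kb of EXA1 the 757 genes become 750. Of the genes in that window 36.9% were called against 36.0% of all genes in MS, 36.4% against 32.4% in NaCl, 33.7% against 34.8% at 23 °C and 30.2% against 28.8% at 39 °C. At least 2-fold in all 4 were 8 genes higher, among them the defensin genes PDF1.2, PDF1.2b, PDF1.2c and PDF1.3, MRD1 and AT1G73600, a methyltransferase gene (2.27, 1.35, 1.81 and 1.71 in MS, NaCl, 23 °C and 39 °C). Lower by as much were 17 genes, among them EXA1, BGL2, FMO1, CYP71A12 and the terpene synthase gene TPS04 (−3.41, −1.67, −3.15 and −2.51). AT1G64795, singled out after its values were seen, had 0 to 7 counts in each of the 12 wild-type libraries and 571 to 2901 in each of the 12 mutant ones.

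Between MS and NaCl 2977 genes were called in the same direction and 572 in opposite directions (correlation of log2 fold changes 0.363), and between 23 °C and 39 °C 2921 and 389 (0.362). For MS and 23 °C they were 2356 and 1045 (0.386), MS and 39 °C 2294 and 577 (0.304), NaCl and 23 °C 2171 and 925 (0.242) and NaCl and 39 °C 1851 and 811 (0.204).

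The 2 unstressed controls differed in most genes. At 23 °C the wild type had more mRNA of the sugar-starvation genes ASN1, at 796 ± 12.7 against 13.1 ± 0.682 CPM in MS (log2 fold change 5.93, SE 0.051, n = 3 per group, adjusted p = 2.68e-67), and SEN1 (4.80, SE 0.045). It also had more of the iron reductase gene FRO6 (4.99, SE 0.178), the cyclin gene CYCP2_1 (4.94, SE 0.159) and the aldolase gene FBA5 (4.75, SE 0.084). KIN1, close in sequence to KIN2 (−6.40, SE 0.214), the ribonuclease gene RNS1 (−5.99, SE 0.132), SQP2 (−5.29, SE 0.211) and DIR5 (−5.17, SE 0.46) were lower. EXA1 itself was higher at 23 °C in the wild type (0.97, SE 0.056), and in exa1-1 it was not called (−0.08, SE 0.097, adjusted p = 0.47, but −0.39 and called with library totals alone).

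All 41 photosynthesis genes were higher at 23 °C in the wild type, 41 adjusted over the list alone (median 1.44, adjusted p = 1.13e-21, estimated 0.0281), PRK of the Calvin cycle by 3.20 (SE 0.044). So were aquaporins, 16 of 18 by either count (median 1.58, adjusted p = 3.07e-09, estimated 0.0189), and autophagy genes, 11 of 12 by either count (median 0.56, adjusted p = 0.000242, estimated 0.0123). Clock genes were higher in 13 of 18 with 2 lower by either count (median 0.77, adjusted p = 0.00922, estimated 0.0218), COR27 by 2.62 (SE 0.05) against GI at −1.77 (SE 0.083). Lower were all 14 ER folding genes, 14 adjusted over the list alone (median −1.46, adjusted p = 1.16e-09, estimated 0.00274), with CNX1 at −2.06 (SE 0.041). The cold list was lower in 10 of 11 by either count (median −3.10, or −2.50 with 1 member at its bound, adjusted p = 1.25e-05, estimated 0.00393), with LTI78 at −3.88 (SE 0.064). Small heat shock genes were lower in 11 of 15 with 1 higher by either count (median −2.25, adjusted p = 1.47e-05, estimated 0.00393) and larger chaperones in 9 of 13 with 2 higher by either count (median −1.64, adjusted p = 2.4e-05, estimated 0.0123), with HSP70 at −3.10 (SE 0.052). Jasmonate genes were lower in 12 of 18 with 2 higher by either count (median −0.71, adjusted p = 0.00346, estimated 0.0189), with JAZ1 at −3.20 (SE 0.076). Pattern-triggered immunity genes were lower in 13 of 19 with 3 higher (median −0.59, adjusted p = 0.0188, estimated 0.0495, and 0.0537 with totals alone). The calls of translation factors (15 of 21 lower, 0.00614, estimated 0.116), shoot markers (7 of 10 higher, 0.0348, estimated 0.0943) and ribosomal proteins by name (12 of 18 lower, 0.00874, estimated 0.184) were lost with an estimated correlation.

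Many of these lists passed in the mutant controls as well. Photosynthesis genes were higher in 41 of 41 (median 1.63, adjusted p = 9.42e-25, estimated 0.0255), aquaporins in 18 of 18 (1.27, 8.36e-11, estimated 0.0159) and autophagy genes in 8 of 12 (0.57, 0.00524, estimated 0.0352), each by either count. ER folding genes were lower in 11 of 14 (−0.80, 5.83e-06, estimated 0.0145), the cold list in 7 of 11 (−1.65, 7.84e-05, estimated 0.0145) and larger chaperones in 9 of 13 (−1.19, 0.000294, estimated 0.0244). Jasmonate genes were lower in 15 of 18 (−0.93, 0.000619, estimated 0.0145) and pattern-triggered immunity genes in 12 of 19 (−0.86, 0.00585, estimated 0.0255), each by either count. Clock genes (0.0915), translation factors (0.106) and shoot markers (0.102) were not called here, though they passed with library totals alone (0.0294, 0.00989 and 0.0481). Of the small heat shock genes 8 of 15 were lower with 2 higher (−0.58, 0.0272), a call lost with an estimated correlation (0.0889) or with totals alone (0.144). Whether the genotypes differ in these control differences was not tested. ASN1 (5.97, SE 0.053), PRK (3.63, SE 0.046) and COR27 (2.12, SE 0.05) were higher, and RNS1 (−6.03, SE 0.148), RAP2.6 (−5.26, SE 0.091) and HSP70 (−2.64, SE 0.052) lower. In all, 14486 of 21917 genes were called in the wild type, 7289 higher and 7197 lower at 23 °C, and 14613 in exa1-1, 7256 and 7357. With library totals alone these were 5213 and 10013, and 4451 and 11362, with the median of all genes at −0.23 and −0.33.

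Salt and heat called 7351 genes in the same direction in the wild type, 3597 up and 3754 down, where independent lists would give 2829.6 and 3150.9, and 4871 in opposite directions (correlation 0.291). In exa1-1 these numbers were 7732, 3634, 4098, 2766.3, 3249.9 and 4553 (0.313). For the genes called in both genotypes the mutant response followed the wild-type one with a slope of 1.045 under salt (13247 genes, correlation 0.953) and 0.974 under heat (15021 genes, 0.958).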

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

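Of the tests below, those of depth, abundant genes, time of day, scaling, organellar RNA, loss of cytosolic messages, the EXA1 region and the regroupings of libraries were chosen after the result was seen. What singles out the first results is a difference between the genotypes in the response to the same stress, by a test of that difference. For salt 4291 genes passed. As lists these were ER folding (adjusted p = 2.7e-09, estimated 0.0138), ABA and osmotic response (1.26e-08, estimated 0.00326), cold (4e-05, estimated 0.0176), ethylene (2.38e-05, estimated 0.0176), root markers (0.00192, estimated 0.0353), and, lost with an estimated correlation, photosynthesis (3.79e-12, estimated 0.214), aquaporins (5.71e-07, estimated 0.0838), small heat shock genes (0.00129, estimated 0.0622), larger chaperones (0.00192, estimated 0.151), auxin genes (0.0113, estimated 0.0669) and cell division (0.0452, estimated 0.22). As genes, the largest differences by the naming rule were GSTU3 (4.31), LTP4 (3.76), LEA7 (3.18), SAG13 (2.90), ELI3-2 (2.79), PDF1.2c (−2.41), RGF9 (−1.45), PDF1.2 (−1.40), BZIP34 (−1.31, not called with log2 FPKM + 1) and SVL2 (−1.29).

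For heat 3533 genes passed the same kind of test. The lists were ER folding (adjusted p = 0.000408, estimated 0.0583), small heat shock genes and larger chaperones (0.00431 each, estimated 0.0583 each), chloroplast-encoded genes (0.0278, estimated 0.0583) and cell division (0.034, estimated 0.106). The calls of larger chaperones and cell division were lost when a trend on coding length and GC content was taken off (0.0751 each). The genes were SAP10 (4.18), GDPD6 (2.93), ELI3-2 (2.65), PMZ (2.17), GSTU25 (1.99), ATHSP22.0 (−6.06), HSP23.6-MITO (−2.81), UGT73C1 (−2.54), SQP1 (−2.47) and XPL1 (−2.31); SAP10, GDPD6 and ATHSP22.0 had no count or 1 count in a group, and the first 2 lose their call without single libraries, SAP10 also with log2 FPKM + 1 and GDPD6 in 7 other settings, as given in the report. Among 100 regroupings of the libraries that keep the design, 2 gave as many interaction genes in each experiment, the real one included. The other was the exchange of the genotypes within 1 condition, with 9126 genes for salt and 8231 for heat, which turns the genotype difference itself into an interaction and so points to that structure of the samples. The remaining regroupings mix genotypes that differ, so they cannot decide on chance.

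With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each of the 10 comparisons of 2 groups only the real split, 1 of 10, gave as many genes as observed: 15407 and 15672 for salt, 16839 and 16622 for heat, 7717, 6950, 7283 and 6030 for genotype in MS, NaCl, 23 °C and 39 °C, and 14486 and 14613 for the controls. The highest other split gave 0, except 1 for the mutant controls.

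The 2 unstressed controls differed in most genes. Unequal depth is argued against, as the mean totals differ by a factor of 1.039, and so is a small set of abundant genes. The share of the 100 most counted (12.03% and 17.74% of counts) allows a common shift of 0.097 log2 in the others, whose quartiles lay 0.96 apart with library totals alone. Clock genes moved 2.313 times as much as random lists of genes at the same level (median absolute log2 fold change 1.091 against 0.472), which could reflect another time of day at harvest. That cannot be told apart from other differences in growth or handling, because each control belongs to 1 experiment.

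Cytosolic ribosomal protein genes, by annotation note, were lower in exa1-1 in MS (median −0.25, 138 of 177 down) and higher at 23 °C (0.29, 132 up and 3 down), with estimated p of 0.227 and 0.151. No single library accounts for this, as the smallest ratio of a median without 1 library to that with all was 0.7596, and neither does scaling, with −0.17 in MS and 0.289 at 23 °C under library totals. These coding sequences are short (median 435 bases), and taking off a trend on length and GC left 0.1617 of the median in MS (−0.04), so a length-linked difference between libraries may account for that part. At 23 °C the ratio was 1.158, which argues against it there. A biological effect of the genotype remains open and untested for both.

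Mitochondrion-encoded transcripts were higher at 39 °C (median 3.27 in the wild type, but 1.793 over 5 well-counted genes, 2.007 with DESeq2 and 1.104 with log2 FPKM + 1). The part of scaling is not decided, as the wild-type median of 2.387 under library totals rests mostly on genes with few counts. A rise of both organelles is argued against by the chloroplast-encoded median of −0.44. So is loss of cytosolic messages alone by the spread of these 5 genes, 1 quartile of which lies 2.082 from their median. Most mitochondrial counts were ribosomal RNA, which need not have been translated. Carry-over of such RNA, an effect of heat on mitochondrial RNA or on its recovery with polysomes remains possible and was not tested.

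Genes near EXA1 were called the same way in all 4 conditions 0.8223 times as often as elsewhere (6 of 198, or 3.03% against 3.69%, exact p = 0.848), with no enrichment of such shared calls there. A linked change that acts elsewhere was not tested.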

How the results depend on the processing

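The counts of genes called stayed within 1.5 times their value in 214 settings, including each omission of 1 library (7717 genes for genotype in MS became 6399 to 7727, 4291 for the salt interaction 3522 to 4513 and 3533 for the heat interaction 2886 to 3951). With the replicate number as a block the salt interaction gave 4447. Only the 2-fold minimum moved them further, by construction: 4794 and 5213 for salt in the wild type and exa1-1, 9035 and 8931 for heat, 520, 473, 566 and 511 for genotype in MS, NaCl, 23 °C and 39 °C, 442 and 357 for the interactions, 4419 and 4307 for the controls. At 2-fold the genes shared by all 4 genotype comparisons were 25 and those shared by salt and heat in the wild type 1797.

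The median difference in response, exa1-1 minus wild type along the wild-type direction, was −0.03 for salt and −0.04 for heat over genes called in the wild type, but 0.085 and 0.05 over genes called in exa1-1, and 0.012 for heat with library totals alone. Choosing the genes in 1 genotype favours that genotype, so the sign has no fixed meaning.

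By camera, which sets a list against all other genes, list tests kept their side of the threshold in 3487 cases. They became weaker in 141, 72 under an estimated correlation, and stronger in 44, and 0 calls reversed. Taking off the trend on coding length and GC content, chosen after the data were examined, made 14 of these weaker and 13 stronger. Medians of lists did turn with library totals alone, as for translation factors in heat, from 0.29 to −0.62 in the wild type and from 0.23 to −0.73 in exa1-1. In heat, where TMM and library totals differ most, EXA1 in exa1-1 (0.18, not called) turned to −0.78 with library totals alone, −0.41 with log2 FPKM + 1 and −0.72 with log2 FPKM + 0.1, which use no composition factor. Of the 1333 called entries of the naming rule, library totals alone lost 33 and changed the sign of 3, DESeq2 lost 34 of the 1331 it tested, and log2 FPKM + 0.1 lost 88 of 1295 and changed the sign of 4; the cause was not tested. Depth limits genes near 0 counts, where folds are given as bounds or ratios.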

Other observations

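The group tests of this part were all chosen after the data were examined. Among annotated processes in exa1-1 in NaCl, genes of electron transport in photosystem I were lower, 11 of 12 down (median −0.78, adjusted p = 1.26e-09 by camera, estimated 0.0437), the only 1 of 11 processes past the preset test that kept its call. In MS, at 23 °C and at 39 °C 33, 32 and 29 processes passed with the preset correlation and 0 with an estimated one. Nuclear genes for chloroplast ribosomal proteins, by annotation note, were lower in exa1-1 in MS in 24 of 36 with 2 higher (median −0.20, adjusted p = 1.79e-05, estimated 0.256) and in NaCl in 24 of 36 with 4 higher (median −0.24, adjusted p = 9.07e-06, estimated 0.276). Cytosolic ribosomal protein genes by note were at 0.11 at 39 °C (66 of 177 up, 12 down, adjusted p = 0.000103, estimated 0.66) and not called in NaCl (adjusted p = 0.982). Heat raised them with TMM by a median of 0.43 in the wild type and 0.29 in exa1-1, which turned to −0.47 and −0.67 with library totals alone.

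Genotype differences followed the length of the coding sequence and, except in NaCl, the GC content of the spliced mRNA. The rank correlation of log2 fold change with length was 0.429 in MS (0.387 to 0.441 without 1 library), 0.183 in NaCl, 0.122 at 23 °C and 0.217 at 39 °C; at 23 °C it fell to 0.051 without WT 23 °C replicate 3 and stood at 0.184 without replicate 1. With GC content it was 0.103, −0.0067, 0.203 and 0.238 in the same order. In MS the 25% of genes with the shortest coding sequence (median 486 bases) had a median of −0.19 and the 25% with the longest (2256 bases) one of 0.14. Taking off a trend of each library on length and GC content left the short small heat shock genes called in MS (median coding length 472.5 bases, median change −0.592 before and −0.403 after, adjusted p = 0.000124). Calls lost that way were those of organellar ribosomal proteins in MS (0.283), in NaCl (0.0766) and with heat in the wild type (0.111) and exa1-1 (0.238). At 39 °C they were those of ABA receptors (0.541), translation factors (0.142), the ABA and osmotic list (0.086) and auxin genes (0.0571), and in the heat interaction larger chaperones and cell division (0.0751 each). Antioxidant genes lost theirs with salt (0.0645 and 0.0828 in the wild type and exa1-1) and in the mutant controls (0.0748), and auxin genes with heat in exa1-1 (0.0753). Lists that newly passed were larger chaperones (0.000262), root markers (0.0248), NLR receptors (0.0393) and ABA receptors (0.0486) in MS and cold (0.0417), salicylate (0.0305) and pattern-triggered immunity (0.0428) lists in NaCl. Another 6 newly passed with heat or in the mutant controls. Whether this reflects the mutation or the preparation of the libraries was not tested.

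The first 4 principal components of the 24 libraries held 52.0%, 26.7%, 9.74% and 2.66% of the variance. The 10 most counted genes took 3.01% to 4.88% of counts in the groups of the salt experiment, 6.13% and 5.56% at 23 °C in the wild type and mutant, and 10.5% at 39 °C in both.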
